A study of Homo sapiens with 8 samples.

How the data were processed

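Total RNA from U373 astrocytoma cells was measured on 8 Affymetrix Human Gene ST arrays, 2 for each of vehicle, 10 nM progesterone, 1 µM RU-486 and both steroids, after 12 h. Per the labels' protocols, the cells were first kept in medium with hormone-free serum, RNA was extracted with Trizol, and biotin-labelled target was made with the manufacturer's whole-transcript protocol. Groups and replicate numbers were taken from the sample titles. The titles and the treatment protocol name RU-486, but the descriptions of those samples give a different compound number, read here as the same drug, and the cell line field gives a shortened form of the name U373 used elsewhere in the labels.

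The authors deposited 1 log2 expression value per probe set and array, for 33297 probe sets. Per the submitters' processing notes, RMA, oligo and limma were used, without versions or settings. RMA, as a method, corrects background, equalises the distribution of values between arrays and summarises probes into probe sets, so that a shift shared by most genes of an array would be removed before deposit and differences of dim genes are compressed. Whether other filters were applied is not given in the sources used here. The 8 array medians ran from 6.93 to 7.02. For arrays the precision is limited by their number, and dim probe sets have no absolute zero.

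Of the probe sets, 19460 pair with 1 gene symbol in the platform annotation, 1754 with several and 12083 are not listed with a gene. 19429 of the first kind matched a RefSeq gene identifier (assembly GRCh38.p14, used for names only), and 0 symbols needed an update. For the 769 genes with several probe sets, the probe set with the highest mean over all arrays was kept, which left 18417 genes. There was no filter on dim genes. Probe sets with several symbols or none were tested apart and gave 0 calls. PGRMC1 and FKBP5 are not analysed here, since no probe set pairs with either alone, and some other genes are not reported here. No genome was used and no coordinates are given.

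Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the group means of all 8 arrays, which share 1 estimate of the spread with 4 residual degrees of freedom. The 9 contrasts are the 6 pairwise ones, the interaction, and the average effects of RU-486 and of progesterone, each over 4 arrays with and 4 without the drug. A moderated F test over the 4 groups gave 0 genes, with 1405 at an unadjusted p under 0.05. P-values were adjusted by Benjamini-Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. Changes are differences of log2 values with their SE.

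31 gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera compares the members with all other genes. The median difference over all genes was 0.03 for the average RU-486 effect, 0.03 for that of progesterone and 0.07 for the combination against vehicle. List medians and counts of members above 0 are to be read beside these values. With an estimated correlation camera called 0 lists in each of the 9 contrasts, with 0 to 4 lists per contrast at an unadjusted p under 0.05. The fry test, which asks whether a list's own genes move one way on balance, called 2 lists for the combination against vehicle, 3 for the combination against progesterone, 1 for RU-486 against progesterone, 6 for the average RU-486 effect and 0 in the other 5 contrasts.

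Genes named in the text follow a rule fixed before the data were examined. For each steroid treatment against vehicle it takes the 12 largest changes each way among called genes whose arrays do not overlap, and for the other contrasts the 5 largest. Where fewer than 5 pass it adds those with the smallest p and no overlap, to 5. It further takes up to 4 members of each list with the smallest p and a fixed set of steroid receptors. Other genes named as members of a list, such as the chaperones, were chosen after their values were seen. Small RNA and uncharacterised genes are counted as classes. Of the 50 genes with the smallest p, small RNA genes made up 18 for the average progesterone effect, 10 for the combination against RU-486, 9 for progesterone against vehicle and 0 for the average RU-486 effect, and uncharacterised genes 1, 2, 5 and 0 in the same order.

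The pipeline was tested on simulated data for 18417 genes with 200 changed genes. For the average RU-486 effect it recovered 55.0% of genes changed by 0.5 log2 units and 93.2% of those changed by 1. For the combination against vehicle it recovered 9.6% and 79.2%. It made 7.4 false calls per run in the first comparison and 4.2 in the second, and with no change 0.2 calls per run. The simulated genes varied independently, with the same spread in all groups and no direction shared by the genes of an array. The real arrays differ in both respects, so these rates may not hold for them.

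Alternatives were the replicate number as a block, leaving out the 25% or 50% dimmest genes, centring each array on its median, quantile normalization, an intensity trend with robust variances, array weights (statmod 1.5.0), all probe sets, the arrays of the compared groups alone, a 1.5-fold minimum, camera with an estimated correlation, fry, and leaving out each array in turn. The within-group axis, the leading direction of the deviations of arrays from their group means, was added as a covariate after seeing the data.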

Results

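Gene expression was measured in U373 cells, an established human astrocytoma line, after 12 h of treatment with vehicle, 10 nM progesterone, the antiprogestin RU-486 (mifepristone) at 1 µM, or both steroids together. Each of the 4 groups had 2 arrays, 8 in all, and total RNA was hybridised to a whole-transcript Affymetrix array. The labels call the replicates biological but do not say that they came from separate cultures, so the p-values measure the spread between these samples. The number of arrays limits the precision of every value. After probe sets were reduced to 1 per gene, 18417 genes were compared on the log2 scale, with means and SD over n = 2 arrays per group.

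Replicates resembled each other closely in 3 groups and less so after progesterone. The SD across genes of the difference between replicates was 0.35 log2 units for progesterone, against 0.18 for vehicle, 0.16 for RU-486 and 0.17 for the combination. In the progesterone pair 2176 genes differed by over 0.5 log2 units, compared with 450, 127 and 183 genes in the same order. The fit gives each gene 1 spread for all groups, which these pairs did not share. SE and p may therefore be too small where progesterone arrays are compared, and too large for RU-486 against vehicle. Counts at an unadjusted p under 0.05 are set below against 921 expected, a number that presumes an equal spread. The direction that held 66.4% of the variance within groups is called the within-group axis here. Progesterone replicate 1 scored 21.8 on it and progesterone replicate 2 scored -24.7. Replicate 1 scored above replicate 2 in the other groups as well, at -3.71 and -18.7 for vehicle. The scores were 4.23 and -3.84 for RU-486 and 16.7 and 8.11 for the combination. Group means on the axis ran from -11.2 for vehicle through -1.42 for progesterone and 0.19 for RU-486 to 12.4 for the combination. Genes of the G2/M phase of the cell cycle had lower expression along the axis (limma camera adjusted p = 1.34e-11), as did interferon response genes (limma camera adjusted p = 0.00026), and Notch and Hedgehog targets had higher expression (limma camera adjusted p = 0.0393). In the same order the adjusted p was 0.128, 0.128 and 1.00 with an estimated correlation. The list of endoplasmic reticulum (ER) stress and amino acid response genes did not pass (limma camera adjusted p = 1.00).

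**Figure D1:**
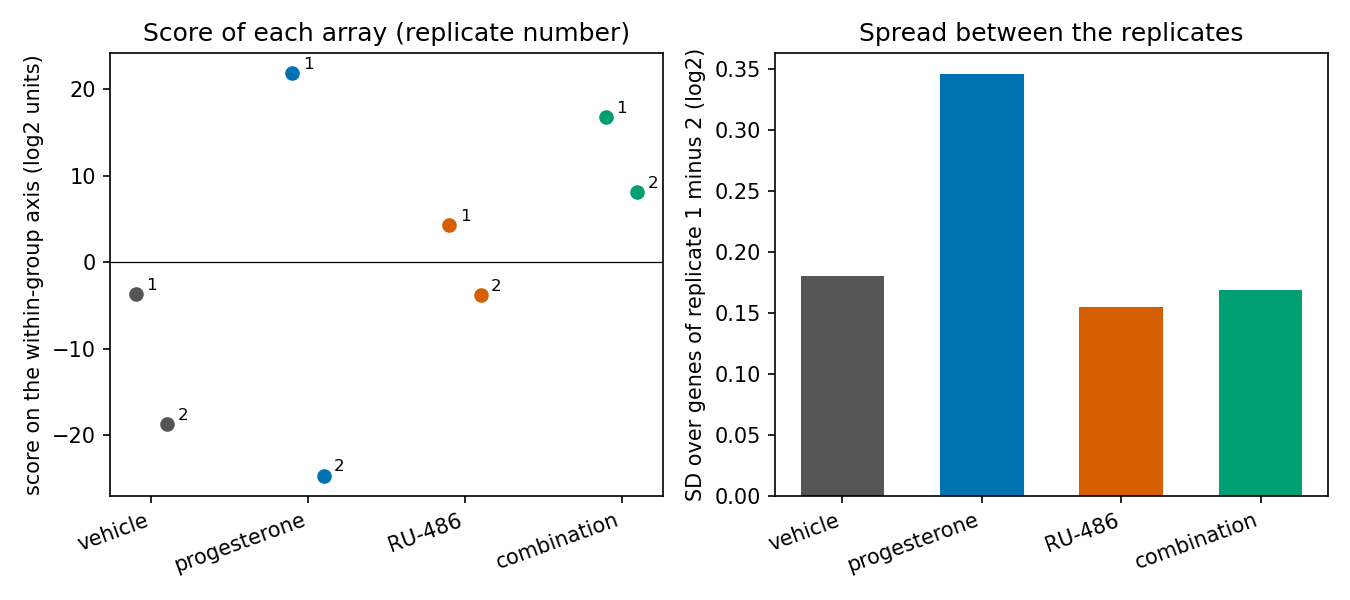
Score of each of the 8 arrays on the within-group axis in log2 units, with the replicate number beside each point (left), and the SD across genes of replicate 1 minus replicate 2 in log2 units as bars from 0 (right). The progesterone arrays lie at 21.8 and -24.7, and their SD of 0.35 is above the 0.16 to 0.18 of the other groups.

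Receptors that bind the 2 steroids were set against the array background, since signals of different probe sets are not comparable as levels. PGR, the nuclear progesterone receptor, had a mean log2 level of 4.60 ± 0.16 (SD, n = 8 arrays), and 48.7% of 341 olfactory receptor genes, which are rarely transcribed outside the nose, lay below it. Their own median was 4.64, so the PGR signal was not above this background, and 95% of them lay below 6.22. Some genes named below also lay under 6.22 on every array, among them PNPLA4, FREM3, PCDHA11, CLRN2, OR2M3, IGFL4, GPR52, CSPG4 and MPEG1. Their differences are those of dim probe sets in the range of this background. NR3C1, the glucocorticoid receptor, which RU-486 also blocks, had a mean log2 level of 9.96 ± 0.21 (SD, n = 8) and lay above every olfactory receptor gene. PGRMC2, a membrane-associated progesterone-binding protein, was measured at 9.65 ± 0.08, and PAQR8, a membrane progestin receptor, at 9.25 ± 0.07. ESR1 and NR3C2, the estrogen receptor alpha and mineralocorticoid receptor genes, were dim, at 5.95 and 5.66. PGRMC1 was not analysed here. Vimentin (VIM), an intermediate filament of astrocytes and mesenchymal cells, was at 13.4, the calcium-binding glial marker S100B at 9.59 and the astrocyte filament gene GFAP at 7.54.

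With RU-486 present, 6 genes rose and 0 fell when the 4 arrays with the drug were compared with the 4 without it, progesterone being balanced on both sides. ASNS, which makes asparagine, rose by 1.14 ± 0.09 log2 units (SE), or 2.21-fold. CPT1A, which commits long-chain fatty acids to mitochondrial oxidation, rose by 1.04 ± 0.09 (2.06-fold), and SLC25A20, the carrier that brings the resulting acylcarnitines into mitochondria, rose by 0.66 ± 0.06. The stress-responsive chromatin regulator NUPR1 rose by 1.01 ± 0.10. CHAC1, an enzyme that degrades glutathione, rose by 0.96 ± 0.07, and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, by 0.94 ± 0.08. The limma adjusted p was 0.0479 for NUPR1 and 0.0237 for each of the other 5 genes. SLC25A20 lies outside the rule that named the other 5 in this comparison.

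Mean ASNS levels were 8.83 ± 0.03 in vehicle, 8.57 ± 0.08 in progesterone, 9.83 ± 0.25 in RU-486 and 9.86 ± 0.02 in the combination (SD, n = 2 each). CPT1A was at 9.82 ± 0.08, 9.71 ± 0.25, 10.7 ± 0.00 and 10.9 ± 0.10 in the same order. The probe sets were 8141150 for ASNS, 7949971 for CPT1A, 8087224 for SLC25A20, 8000574 for NUPR1, 7982868 for CHAC1 and 7973530 for PCK2. The number of genes past the threshold depended on single arrays. It was 0 without vehicle replicate 1, vehicle replicate 2, RU-486 replicate 2, combination replicate 1 or combination replicate 2, it was 1 without RU-486 replicate 1, and it was 998, of which 261 rose and 737 fell, without progesterone replicate 1. With each array left out, the log2 differences of the 6 genes stayed between 0.64 and 1.23. Over all probe sets 0 were called, and with quantile normalization NUPR1 was not (limma adjusted p = 0.0595).

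**Figure D2:**
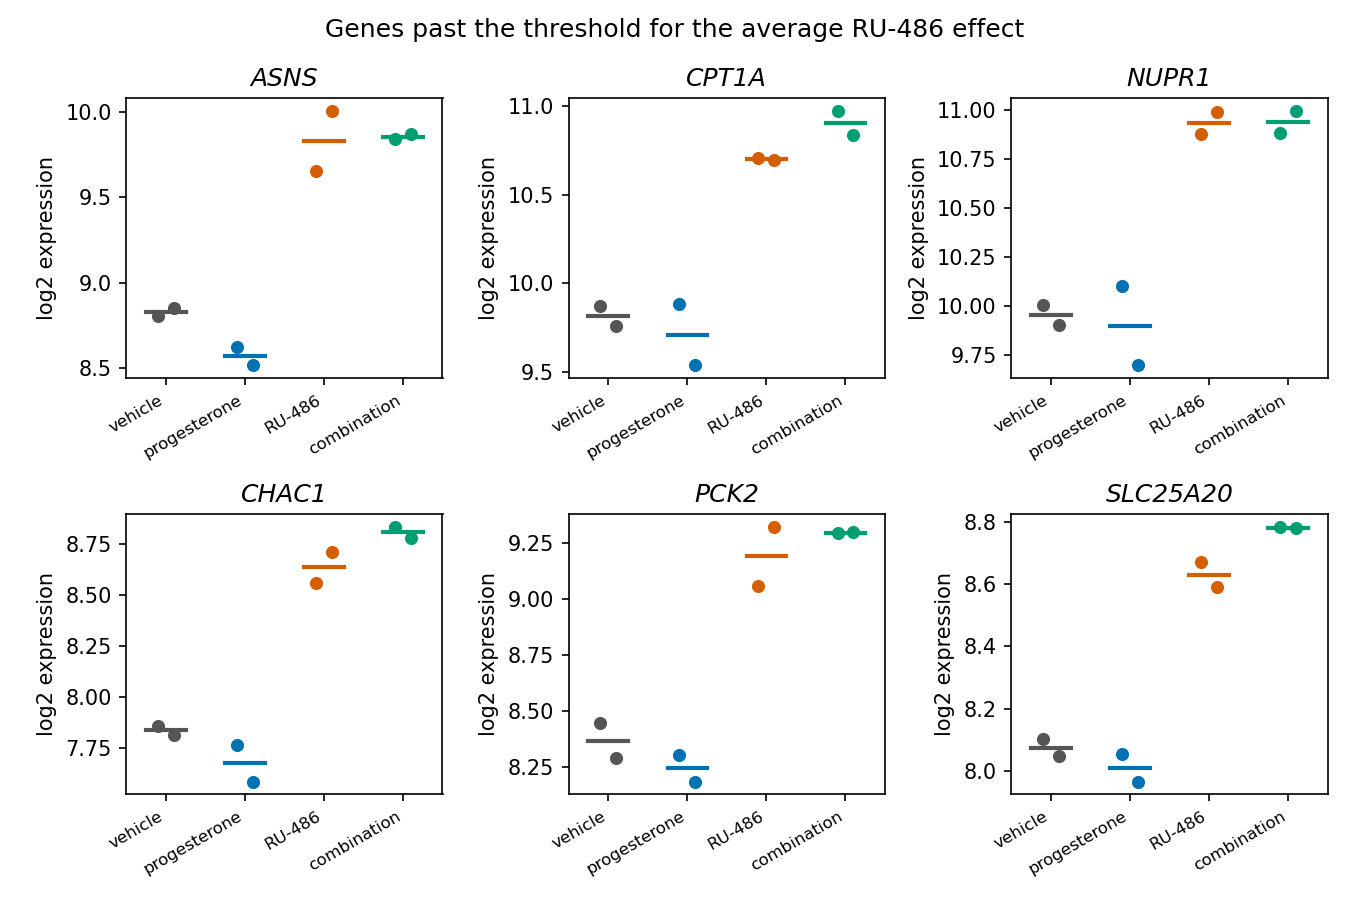
Log2 expression of the 6 genes past the threshold for the average RU-486 effect, with 1 point per array, a line at the mean of each group of 2 arrays, and an axis range of its own in each panel. The 4 arrays with RU-486 lie above the 4 without it in every panel, as for ASNS at 9.83 and 9.86 against 8.83 and 8.57.

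For the average RU-486 effect, genes that respond to amino acid shortage or ER stress were the list that moved most. Of its 24 measured members 23 had a higher mean with the drug, the median log2 difference was 0.30, and 2 members, ASNS and CHAC1, passed among all genes. Adjusted over the list alone, 15 members rose and 1 fell. The serine synthesis genes PSAT1 and PHGDH differed by 0.82 (limma adjusted p = 0.0730) and 0.83 (limma adjusted p = 0.0794), and ATF4, the transcription factor that drives much of this response, by 0.49 (limma adjusted p = 0.0794), none of which passed among all genes. Among its chaperones and folding factors, HSPA5 was at 0.14, PDIA4 at 0.09, DNAJB9 at 0.09, EDEM1 at 0.05 and SDF2L1 at 0.03, and HSP90B1, at -0.26, was the member that fell. The limma camera adjusted p of the list was 1.72e-15, and the adjusted p was 0.214 with an estimated correlation.

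3 other lists were higher with RU-486 as sets, where the median over all genes was 0.03. The NRF2 and metallothionein list, genes of oxidant and metal defence, had a median difference of 0.17 with 18 of 18 members higher (limma camera adjusted p = 4.03e-07). Adjusted over the list alone, 5 members rose and 0 fell: HMOX1, SRXN1, GCLC, TXNRD1 and MT1F. Glucocorticoid receptor targets had a median of 0.09 with 31 of 39 higher (limma camera adjusted p = 0.00342). SGK1, a kinase induced by steroids, differed by 0.37 ± 0.06 and was the 1 member that passed when adjusted over the list alone. These 2 lists share 4 genes. Immediate early genes had a median of 0.09 with 19 of 25 higher (limma camera adjusted p = 0.00524), and when adjusted over the list alone 6 members rose and 1, EGR1, fell. The immediate early call ended without progesterone replicate 2 (limma camera adjusted p = 0.0765) and with the axis as covariate (limma camera adjusted p = 0.0746). DUSP6, a phosphatase that restrains ERK signalling, differed by 0.57 ± 0.12. With an estimated correlation the adjusted p of these lists was 0.319, 0.382 and 0.876.

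4 lists were lower with RU-486 as sets. G2/M genes had a median log2 difference of -0.26 with 23 of 29 members lower (limma camera adjusted p = 3.85e-09). Adjusted over the list alone, 3 members fell and 0 rose: the spindle gene DLGAP5, at -0.83 ± 0.18, and the checkpoint kinases BUB1B and BUB1, at -0.27 ± 0.06 and -0.30 ± 0.07. This list also moved with the within-group axis, on which the mean was 0.19 for RU-486 and -11.2 for vehicle, with overlap between their arrays. Replication-dependent histones had a median of -0.14 with 16 of 17 lower (limma camera adjusted p = 1.24e-08), and 1 member, the linker histone H1-3, fell when adjusted over the list alone. The cholesterol efflux list, targets of the liver X receptor, had a median of -0.07 with 7 of 9 lower (limma camera adjusted p = 0.000247). In it ABCA1, the cholesterol exporter, stood at -0.74 ± 0.10 (limma adjusted p = 0.112) and SREBF1, a regulator of lipid synthesis, at -0.47 ± 0.06 (limma adjusted p = 0.0794), and both fell when adjusted over the list alone, with ABCG1 and MYLIP. Interferon response genes had a median of -0.05 with 16 of 24 lower (limma camera adjusted p = 0.0187), and this list too moved with the axis. The interferon call ended without progesterone replicate 2 (limma camera adjusted p = 0.462) and with the axis as covariate (limma camera adjusted p = 0.428). With that covariate the median was -0.13 for G2/M genes, -0.17 for cholesterol efflux genes and -0.02 for interferon response genes. Without the covariate and with an estimated correlation, the camera adjusted p was 0.382 for G2/M genes and 0.214 for histones. It was 0.214 for cholesterol efflux and 0.615 for interferon response genes.

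The other 23 lists were not called for the average RU-486 effect. Progesterone receptor targets known from breast and endometrium had a median of 0.07, and adjusted over the list alone 4 members rose and 0 fell: SGK1, TSC22D3, KLF4 and MYC. The median was 0.07 for xenobiotic targets of PXR and AhR, 0.08 for neurosteroid synthesis genes, 0.05 for steroid receptors, 0.04 for cholesterol synthesis genes and 0.02 for G1/S genes. The medians were 0.02 for p53 targets, 0.01 for apoptosis regulators, 0.05 for hypoxia and glycolysis, 0.05 for NF-kappaB targets and cytokines, 0.04 for TGF-beta targets, 0.003 for extracellular matrix and invasion genes, 0.04 for glioma growth factors and receptors and 0.08 for Notch and Hedgehog targets. Ribosomal proteins had a median of 0.03, oxidative phosphorylation genes 0.04 and circadian clock genes 0.04. Markers of astrocytes and glioma stem cells had a median of -0.02, neurons 0.06, oligodendrocytes 0.006, microglia and leukocytes 0.04, endothelium 0.10 and epithelium 0.001. In 7 of these lists (steroid receptors, G1/S, apoptosis, TGF-beta, extracellular matrix, oligodendrocytes and epithelium) the median was above 0 while camera's direction was down. The median over all genes was itself 0.03, and camera compares a list with all other genes. GDF15, a stress-induced cytokine, at 1.02 ± 0.16 (limma adjusted p = 0.172), and VEGFA, the vascular growth factor, at 0.45 ± 0.07 (limma adjusted p = 0.170), did not pass among all genes and passed when adjusted over their lists alone.

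RU-486 alone was compared with vehicle to show the effect of the antagonist without added hormone. Among the higher genes with the smallest p were ASNS at 1.00 ± 0.12 (SE), NUPR1 at 0.98 ± 0.14, CPT1A at 0.89 ± 0.13, PCK2 at 0.82 ± 0.11 and CHAC1 at 0.80 ± 0.10. Among the lower ones were the testis linker histone H1-6 at -0.70 ± 0.10, ABCA1 at -0.64 ± 0.14, the olfactory receptor OR2M3 at -0.61 ± 0.09, SREBF1 at -0.55 ± 0.08 and the protease gene PRSS35 at -0.44 ± 0.08. None of these passed, and the smallest limma adjusted p was 0.484, with 0 genes called. At an unadjusted p under 0.05 lay 571 genes, where 921 are expected by chance if all groups vary alike.

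As sets, 6 lists were higher and 5 lower after RU-486 alone. The ER stress and amino acid list had a median of 0.20 (limma camera adjusted p = 3.80e-11), and 8 members rose and 0 fell when adjusted over the list alone, among them TRIB3, a pseudokinase induced by ATF4, at 0.73. The NRF2 and metallothionein list had a median of 0.22 with 18 of 18 higher, and the metallothionein MT1F, at 0.52 ± 0.12, passed over the list alone. Glucocorticoid receptor targets (median 0.11), PXR and AhR targets (0.11) and progesterone receptor targets (0.09) were higher too, and the first and last of these share 9 genes. Markers of microglia and leukocytes were higher with a median of 0.11 in 15 of 15 genes (limma camera adjusted p = 0.00318). These are mostly dim probe sets, with a mean log2 level of 5.76. Lower were histones (-0.17), G2/M genes (-0.18), cholesterol efflux genes (-0.10), G1/S genes (-0.07) and cholesterol synthesis genes (-0.03). ABCA1, ABCG1, MYLIP and SREBF1 fell when adjusted over the efflux list alone. The smallest adjusted p of any list was 0.245 with an estimated correlation, and without vehicle replicate 1 the count of lists was 7.

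Adding RU-486 to progesterone, the combination against progesterone alone, had ASNS, CPT1A and CHAC1 among the largest differences, as RU-486 against vehicle did. ASNS was higher by 1.28 ± 0.12, CPT1A by 1.20 ± 0.13, CHAC1 by 1.13 ± 0.10, SESN2, a stress-induced inhibitor of mTORC1 signalling, by 0.88 ± 0.09 and SLC25A20 by 0.77 ± 0.08. Their limma adjusted p of 0.0777 did not pass. Lower without passing were ABCA1 at -0.83 ± 0.14, SEMA6D, an axon guidance gene, at -0.76 ± 0.13, the protocadherin pseudogene PCDHB18P at -0.54 ± 0.09, the receptor gene GPR52 at -0.53 ± 0.08 and IGFL4 at -0.49 ± 0.08. In the ER stress and amino acid list 18 members rose and 1 fell when adjusted over the list alone, with a median of 0.37 (limma camera adjusted p = 2.92e-13). Immediate early genes (median 0.16) and the NRF2 and metallothionein list (0.15) were also higher, and G2/M genes (-0.22), cholesterol efflux genes (-0.13) and histones (-0.11) were lower. The smallest adjusted p was 0.555 with an estimated correlation. No gene passed in limma, where 2686 genes had an unadjusted p under 0.05 against 921 expected if all groups varied alike. Without progesterone replicate 1 the count of genes was 1090, and without progesterone replicate 2 the count of lists was 3.

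**Figure D3:**
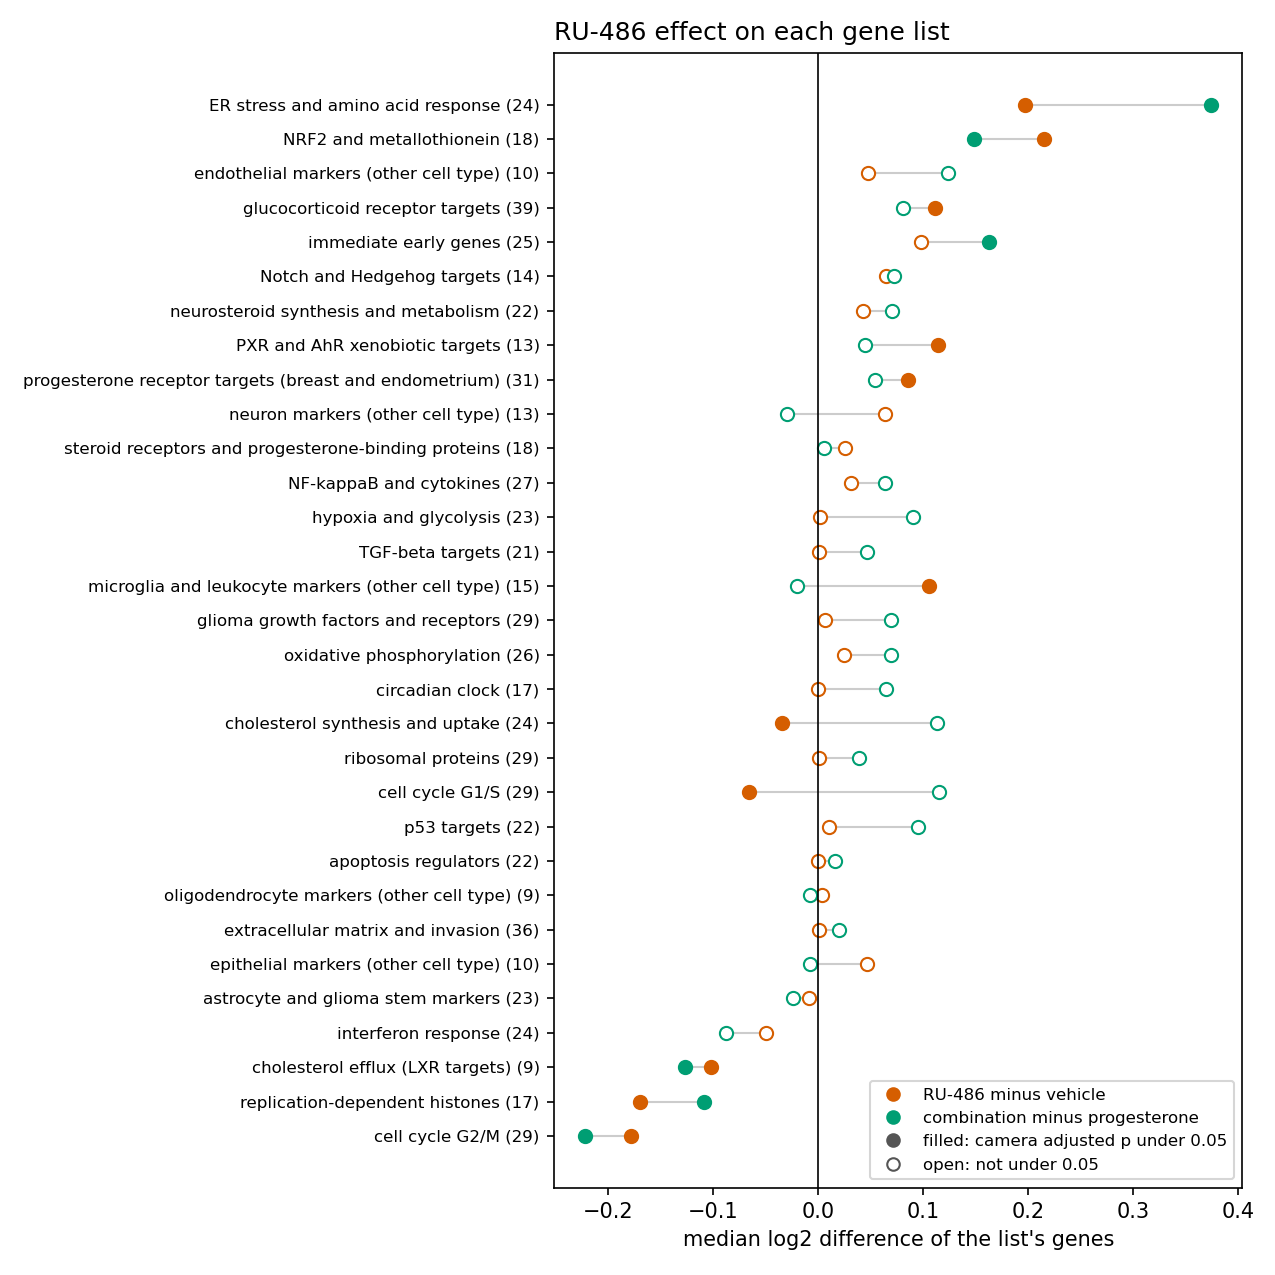
Median log2 difference of each of the 31 gene lists (number of measured genes in brackets) for RU-486 minus vehicle and combination minus progesterone, with filled points where the limma camera adjusted p was under 0.05 and lists sorted by the average RU-486 effect. The ER stress and amino acid list lies at 0.20 and 0.37, and the G2/M list at -0.18 and -0.22.

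Both steroids together, set against vehicle, gave differences that were wider across the array than those of either steroid alone. Over 1.5-fold lay 703 genes, compared with 44 for RU-486 and 46 for progesterone. CPT1A was higher by 1.09 ± 0.13, ASNS by 1.03 ± 0.12, CHAC1 by 0.97 ± 0.10, MST1, a gene for a hepatocyte growth factor-like protein, by 0.78 ± 0.09 and SLC25A20 by 0.71 ± 0.08 (limma adjusted p = 0.205 each, not passed). ABCA1 at -0.85 ± 0.14, SEMA6D at -0.76 ± 0.13, ARRDC3, an arrestin-domain regulator of receptor trafficking, at -0.60 ± 0.11, OR2M3 at -0.58 ± 0.09 and H1-6 at -0.57 ± 0.10 were lower without passing. NR3C1 itself stood at -0.44 ± 0.12 (limma adjusted p = 0.374). The ER stress and amino acid list was higher, with a median of 0.31, and 14 members rose and 1 fell when adjusted over the list alone. G2/M genes (median -0.32) and histones (-0.22) were lower, and the smallest adjusted p was 0.447 with an estimated correlation. On the within-group axis the combination and vehicle means lay farthest apart, at 12.4 and -11.2. In limma 0 genes passed, and 2432 had an unadjusted p under 0.05 against 921 expected. Without combination replicate 1 the count of lists was 5.

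Progesterone alone was compared with vehicle to show the effect of the hormone at 10 nM. No gene passed (smallest limma adjusted p = 0.397). At an unadjusted p under 0.05 lay 1129 genes, against 921 expected if all groups varied alike, which the progesterone pair did not. Higher without passing were PNPLA4, a lipid hydrolase gene, at 0.63 ± 0.12, FREM3 at 0.60 ± 0.09, PCDHB18P at 0.51 ± 0.09, the protocadherin PCDHA11 at 0.49 ± 0.08 and CLRN2 at 0.48 ± 0.08. Of these, PNPLA4, FREM3, PCDHA11 and CLRN2 were dim, under a log2 level of 6.22 on every array, in the range of the background. Lower were the mitochondrial import gene TIMM23 at -0.58 ± 0.11, the cytokine gene IL18 at -0.58 ± 0.12, the Wnt-pathway receptor LGR5 at -0.48 ± 0.09, FAM216A at -0.48 ± 0.10 and the inflammatory caspase CASP4 at -0.37 ± 0.08. PGR differed by 0.22 ± 0.14 and NR3C1 by -0.08 ± 0.12. Progesterone receptor targets had a median of 0.005 with 16 of 31 higher and were not called (limma camera adjusted p = 0.669), and glucocorticoid receptor targets had a median of -0.003. Without progesterone replicate 2 the limma count was 1228, a fit that rests on 1 progesterone array assumed to vary like the other groups.

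As sets, 6 lists were lower and 1 higher after progesterone alone. Cholesterol synthesis genes had a median of -0.14 with 22 of 24 lower (limma camera adjusted p = 0.000181), among them the sterol genes MSMO1 at -0.18 ± 0.08 and HMGCS1 at -0.21 ± 0.10. ER stress and amino acid genes had a median of -0.10 with 18 of 24 lower (limma camera adjusted p = 0.000508), with DNAJB9 at -0.44 ± 0.11 and DDIT3 at -0.36 ± 0.10. Oxidative phosphorylation genes (-0.04), histones (-0.07), G1/S genes (-0.05) and immediate early genes (-0.06) were lower as well. Markers of microglia and leukocytes were higher, with a median of 0.16 in 15 of 15 genes (limma camera adjusted p = 0.000508), at a mean log2 level of 5.76. Against the vehicle mean their median was 0.23 on progesterone replicate 1 and 0.06 on replicate 2. Marker lists of other cell types were also higher on replicate 1. In the same order oligodendrocyte markers were at 0.27 and -0.05 and epithelial markers at 0.20 and 0.01. In the 7 called lists 0 members passed when adjusted over the list alone, and the smallest adjusted p was 0.625 with an estimated correlation. Of the 7 lists 4 kept their call without progesterone replicate 1, and 1 kept it without progesterone replicate 2. Without progesterone replicate 2 the median of the immediate early genes was 0.06, so the sign of their median rests on that array, while camera's direction stayed down. The count of lists called was 3 without vehicle replicate 1 and 3 without progesterone replicate 2.

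Adding progesterone to RU-486, the combination against RU-486 alone, gave 0 genes past the threshold (smallest limma adjusted p = 0.769) and 874 at an unadjusted p under 0.05, below the 921 expected. The ATPase-related gene DQX1 at 0.51 ± 0.08 and PLEKHO1, which encodes a casein kinase-interacting protein, at 0.38 ± 0.08 were among the higher genes, and the zinc finger gene ZNF487 at -0.61 ± 0.12 and MPEG1, a macrophage pore-forming protein, at -0.37 ± 0.08 among the lower ones, all without passing. Of the 31 lists 0 were called by limma's camera, 0 by fry and 0 with an estimated correlation, and 5 had an unadjusted camera p under 0.05. The count was 3 without RU-486 replicate 2, 2 without combination replicate 2, 0 without RU-486 replicate 1 and 1 without each of the other arrays.

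For the average progesterone effect, 4 arrays with the hormone against 4 without, 0 genes passed (smallest limma adjusted p = 0.722) and 926 had an unadjusted p under 0.05, against 921 expected. CSPG4, a proteoglycan of glial progenitors, differed by 0.31 ± 0.06 and ETV1, an ETS transcription factor, by -0.34 ± 0.08, without passing. Here 5 lists were lower: histones (median -0.06, limma camera adjusted p = 0.00229), cholesterol synthesis (-0.01), NRF2 and metallothionein (-0.03), ribosomal proteins (-0.02) and oxidative phosphorylation (-0.01). These are lower against all other genes, where the median over all genes was 0.03. The smallest adjusted p was 0.814 with an estimated correlation, and without vehicle replicate 1 the count of lists was 0. The count was 3, 3, 1, 2 and 3 without progesterone replicate 2, RU-486 replicates 1 and 2 and combination replicates 1 and 2, in that order.

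The interaction asks whether the effect of RU-486 differed with and without progesterone. No gene passed (smallest limma adjusted p = 0.828), and 972 had an unadjusted p under 0.05. SESN2 had an interaction of 0.65 ± 0.13, as it was higher with RU-486 by 0.88 in the presence of progesterone and by 0.22 in its absence, and was the 1 gene of its list that passed when adjusted over the list alone. HSD17B7P2, a pseudogene of a sterol reductase, at 1.05 ± 0.19 and RPL26L1, a ribosomal protein-like gene, at 0.53 ± 0.12 had positive interactions and ZNF487 at -1.11 ± 0.18 and GPR52 at -0.69 ± 0.12 negative ones, none of which passed. For the 6 genes that rose with RU-486 the median interaction was 0.26, and none passed the test of the interaction. The 95% interval ran from -0.12 to 0.69 for ASNS and from 0.01 to 0.65 for CHAC1, and those of the other 4 genes included 0. As sets, the ER stress and amino acid list (median 0.18, 20 of 24 positive), the cholesterol synthesis list (0.19, 22 of 24) and the G1/S list (0.17, 26 of 29) had positive interactions and markers of microglia and leukocytes a negative one (-0.15, 12 of 15 negative). The adjusted p of each was 0.940 with an estimated correlation.

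Progesterone and mifepristone share a steroid skeleton, and mifepristone carries dimethylaminophenyl and propynyl groups that progesterone lacks. The doses were not matched, since RU-486 was given at 100 times the concentration of progesterone. Against vehicle, ASNS differed by 1.00 with RU-486 and -0.26 with progesterone, CHAC1 by 0.80 and -0.16, CPT1A by 0.89 and -0.10, and NUPR1 by 0.98 and -0.05. The direct difference between the steroids was 1.26 for ASNS (95% interval 0.97 to 1.55, limma adjusted p = 0.178) and 0.99 for CPT1A (0.70 to 1.29, limma adjusted p = 0.322), neither of which passed. SREBF1 was lower with RU-486 than with progesterone by -0.54 ± 0.08, and the keratin gene KRT15 by -0.56 ± 0.11, also without passing. Of the lists, 6 were higher and 4 lower with RU-486 than with progesterone, led by ER stress and amino acid genes (median 0.26), NRF2 and metallothionein (0.25) and cholesterol efflux (-0.14). The smallest adjusted p was 0.173 with an estimated correlation. Without progesterone replicate 2 the count of lists was 3.

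Across genes, the RU-486 effect without progesterone correlated with the effect in its presence at Pearson r = 0.407 and Spearman rho = 0.176, from arrays that are not shared. The progesterone effect without and with RU-486 gave Pearson r = 0.137 and Spearman rho = 0.0921. Genes are not independent replicates, so no p-value is given. Each value rested on single arrays: the first was -0.029 without progesterone replicate 2, 0.117 without vehicle replicate 2 and 0.267 without RU-486 replicate 1. The second was -0.37 without progesterone replicate 1, -0.09 without vehicle replicate 2, 0.306 without vehicle replicate 1 and 0.380 without progesterone replicate 2. The effects of progesterone and of RU-486 against the shared vehicle arrays correlated at 0.504, where unchanged groups sharing those arrays gave 0.499 in simulation. Their covariance was 0.0116 against 0.00974 simulated. The simulated genes varied independently, unlike the real ones, so the closeness of the 2 correlations does not show that the shared arrays account for the observed one. Without progesterone replicate 1 the observed correlation of progesterone and RU-486 effects was -0.10.

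**Figure D4:**
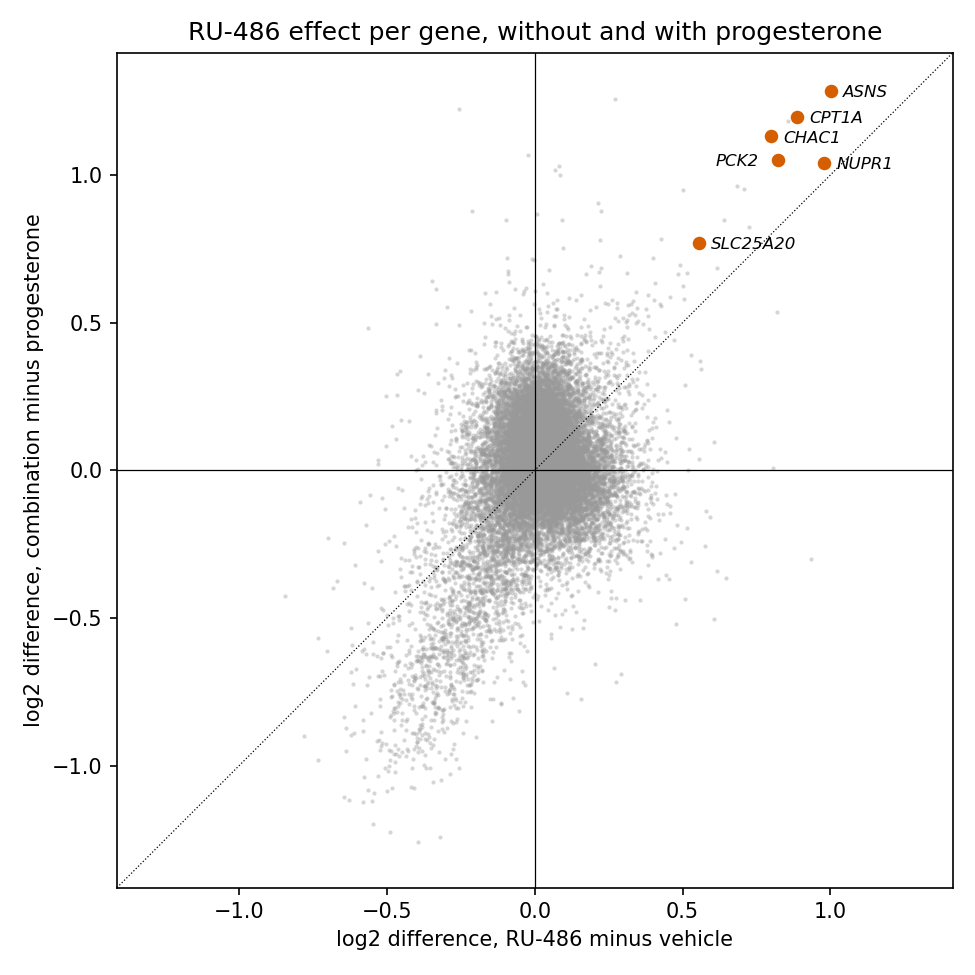
Log2 difference per gene for RU-486 minus vehicle (horizontal) and combination minus progesterone (vertical), with 1 grey point for each of 18417 genes, the 6 genes past the threshold for the average RU-486 effect in orange, and equality as a dotted line. The orange genes lie at the upper right, as for ASNS at 1.00 and 1.28, apart from a cloud of points around 0 and a tail toward the lower left.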

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

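The interaction tests in this part were planned, and none was chosen after the result was seen. 4 gene lists differed between the RU-486 effect with progesterone and the effect without it by the test of that difference itself. In the ER stress and amino acid list the RU-486 effect was larger with progesterone, with a median interaction of 0.18 (limma camera adjusted p = 0.000308) in 20 of 24 genes, and this call held with each array left out in turn. Genes of cholesterol synthesis had a median interaction of 0.19 (limma camera adjusted p = 0.00395), and the interaction call ended without RU-486 replicate 1 (limma camera adjusted p = 0.0712), without progesterone replicate 2 (limma camera adjusted p = 0.169) and with the dimmest 50% of genes left out (limma camera adjusted p = 0.218). G1/S genes had a median interaction of 0.17 (limma camera adjusted p = 0.00153), and the interaction call ended without progesterone replicate 1 (limma camera adjusted p = 0.0929) and with the dimmest 50% of genes left out (limma camera adjusted p = 0.105). Markers of microglia and leukocytes, mostly dim, had a median interaction of -0.15 (limma camera adjusted p = 0.00445), and the interaction call ended without progesterone replicate 1 (limma camera adjusted p = 0.181) and without vehicle replicate 2 (limma camera adjusted p = 0.122), and could not be tested with the dimmest 50% of genes left out, which left too few members. The adjusted p of all 4 was 0.940 with an estimated correlation, and fry called 0 lists for the interaction. Among the 35 splits of the arrays into 4 and 4, the 1 that parts vehicle and combination from the rest called 3 lists. The highest count of any split was 9, so chance is not excluded.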

How the results depend on the processing

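The fit with the within-group axis as covariate was added after seeing the data, and the other alternatives were planned. For the average RU-486 effect, 6 genes were called, all higher. The count was 12 (1 lower) with the dimmest 25% and 24 (2 lower) with the dimmest 50% of genes left out, 11 (0 lower) with median centring, 43 (6 lower) with a trend and robust variances, 11 (2 lower) with the axis covariate, 7 (0 lower) with array weights, 5 (0 lower) with quantile normalization, where NUPR1 was not called (limma adjusted p = 0.0595), and 0 over all probe sets, where more tests are adjusted for. For the combination against progesterone, 0 genes became 6 with the 50% filter, 1 with centring, 17 with trend and robust variances and 17 with the axis covariate. For the combination against vehicle array weights gave 7 genes, and for RU-486 against vehicle 3. RU-486 against progesterone gave 1 gene with trend and robust variances and 2 with the axis covariate, and the F test gave 4 and 1. Filters test fewer genes, and the cause of the other shifts was not tested.

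The titles share replicate numbers across groups but do not say that these pair the arrays. Replicate differences correlated between groups at 0.197 to 0.511 over 6 pairs of groups, a hint from the data at pairing. On the within-group axis, too, replicate 1 scored above replicate 2 in every group. With the replicate number as a block, 6 genes were called for the average RU-486 effect, 4 of them shared. PCK2 (limma adjusted p = 0.0556) and NUPR1 (limma adjusted p = 0.0844) were not called, and ABCA1 and SLC39A10, the latter outside the naming rule, fell. The block gave 1 gene for the combination against vehicle, 1 list for the combination against RU-486 and 1 for the average progesterone effect.

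With an estimated correlation camera called 0 lists in every contrast. Fry called 0 for progesterone and RU-486 against vehicle, the interaction and the average progesterone effect, 3 for the combination against progesterone and 1 for RU-486 against progesterone. With the 50% filter the lists numbered 3 for progesterone against vehicle, 3 for the combination against progesterone, 2 for the combination against RU-486, 6 for RU-486 against progesterone, 2 for the interaction, 5 for the average RU-486 effect and 1 for that of progesterone. Trend and robust variances gave 3 for the combination against RU-486, and the axis covariate 6 for the combination against vehicle. With the 50% filter the correlation of RU-486 effects was 0.665 and that of progesterone and RU-486 effects against vehicle 0.294.

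With each array left out, the lone array being assumed to vary like the other groups, gene counts ran from 0 to 998 for the average RU-486 effect (998, of which 737 fell, without progesterone replicate 1, 1 without RU-486 replicate 1, 0 without either vehicle or either combination array or RU-486 replicate 2), 0 to 1228 for progesterone against vehicle (1228 without progesterone replicate 2) and 0 to 1090 for the combination against progesterone (1090 without progesterone replicate 1). Lists ran from 6 to 10 for the average RU-486 effect, 0 to 7 for that of progesterone, 3 to 9 for progesterone, 7 to 11 for RU-486 and 3 to 5 for the combination against vehicle, 3 to 7 for the combination and 3 to 12 for RU-486 against progesterone, 0 to 3 for the combination against RU-486 and 3 to 5 for the interaction. Correlations ran from -0.029 to 0.569 for RU-486 effects, -0.37 to 0.380 for progesterone effects and -0.10 to 0.704 for both against vehicle, and the negative ones came without progesterone replicate 2 for the first, without progesterone replicate 1 (-0.37) and vehicle replicate 2 (-0.09) for the second, and without progesterone replicate 1 for the last. Over 90 results of named genes and up to 16 alternatives, 1285 kept their side of the threshold, 60 passed it, 32 lost it and 0 reversed. These genes were named only where the compared arrays did not overlap, so leaving out 1 array could not reverse a sign. The replicate block, the filters, the trend and the array weights leave the group differences unchanged. Most of these results had not passed in the main fit, so the counts say little about robustness. Dim genes near the array background limit what can be seen of PGR and the leukocyte markers.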

Other observations

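The list of genes related to fatty acid metabolism, the synthetase lists, the axis covariate and the tests of the 6 genes without progesterone arrays and of the synthetases were chosen after seeing the data. Genes related to fatty acid metabolism, other than CPT1A and SLC25A20 and not all of them oxidation enzymes, were higher with RU-486 as a set. Of 20 other targets of the peroxisome proliferator-activated receptors (PPAR), 18 had a higher mean, with a median log2 difference of 0.13 and a limma camera adjusted p of 0.000949 over the 3 added lists (0.000633 before adjustment). The adjusted p was 0.0573 with an estimated correlation. FABP4, a fatty acid carrier, differed by 0.76 ± 0.15 (SE), ACAA2, a thiolase of mitochondrial beta-oxidation, by 0.30 ± 0.06 and ACSL1, which activates long-chain fatty acids, by 0.23 ± 0.06, while ACADM, the medium-chain dehydrogenase, stood at -0.26 ± 0.10. None of these passed among all genes. At an unadjusted limma p under 0.05, 6 of the 20 were higher. The PPAR targets PDK4, ANGPTL4 and PLIN2 were not among them, at 0.14 ± 0.12, 0.16 ± 0.15 and 0.05 ± 0.09. A hypothesis is that PPAR targets as a group may respond to RU-486 in these cells, and the value of 0.000633 goes with it, although the call ends with an estimated correlation.

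Enzymes that charge transfer RNAs were higher with RU-486 as well. Of 19 cytosolic aminoacyl-tRNA synthetases 18 had a higher mean, with a median of 0.12 (limma camera adjusted p = 2.26e-09), led by YARS1 at 0.73 ± 0.08, AARS1 at 0.56 ± 0.08, CARS1 at 0.56 ± 0.07 and GARS1 at 0.52 ± 0.07, none of which passed among all genes. The list's adjusted p was 0.0573 with an estimated correlation. The hypothesis tested was that the cytosolic enzymes moved and the mitochondrial ones did not. The mitochondrial median was 0.09, under the bound of 0.1 set for it, but limma's camera called that list higher too, in 16 of 16 genes (limma camera adjusted p = 0.00151). The adjusted p of the mitochondrial list was 0.174 with an estimated correlation, and in RU-486 against vehicle 7 of its 16 members were higher, with a median of -0.01. The medians of the average effect differed by 0.0323. At an unadjusted limma p under 0.05, 9 of 19 cytosolic and 1 of 16 mitochondrial members were higher for the average effect. In RU-486 against vehicle these counts were 8 and 0. The larger changes were thus among cytosolic enzymes, and whether the change is confined to them stays open. This test and the rules for reading it were set after the result was seen.

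The 6 genes that rose with RU-486 were weighed against the array differences. With the within-group axis as covariate their median log2 difference was 0.932 of that without it, and the lowest 95% interval bound was 0.516. The genes were called on these same arrays, where a small spread within groups helps a call and favours genes that follow the axis little. This fit therefore cannot decide whether the axis plays a part. In RU-486 against vehicle, which holds no progesterone array, their median was 0.85, so the difference was also present without progesterone replicate 1. That comparison is part of the average effect that picked the genes, so it is not an independent test. Of the 35 splits of the arrays into 4 and 4, 2 called as many genes, the real one with 20 in this 2-group fit and another with 980, so chance is not excluded. That other split parts the arrays with negative axis scores from those with positive ones and points to a structure of the samples, while an effect of RU-486 stays open as a hypothesis.

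Lower G2/M and histone lists with RU-486 were weighed against the same axis. For histones the median with the axis as covariate was 1.13 times that without it (limma camera adjusted p = 2.54e-05). Between the progesterone arrays, which lay farthest apart on the axis, the histone median differed by -0.004. This argues against the axis only as far as that 1 pair shows it. For G2/M genes the median with the covariate was 0.488 of that without it, at -0.13 (limma camera adjusted p = 1.57e-07). A part that follows the axis and a part that follows RU-486 therefore cannot be told apart with 2 arrays per group. For gene lists of the average RU-486 effect 3 of 35 splits called as many as the real 8, with 9 as the highest other, so chance is not excluded.

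The lists that shifted with progesterone alone were weighed against its unlike replicates. Of 7 lists, 4 kept their direction and call without progesterone replicate 1, and 1 kept them without progesterone replicate 2. An effect of progesterone and the difference between its 2 arrays cannot be told apart here, since no further array shows which is typical. For the average progesterone effect 16 of 35 splits called as many lists as the real 4 in this 2-group fit (5 in the fit with all groups), with 9 as the highest other, so chance is not excluded. For genes the real count was 0, which all 35 splits reach by construction (highest other 980), so that count says nothing about chance.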
